A study of Homo sapiens with 10 samples.

How the data were processed

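Gene expression was measured in 10 subclones of U87MG, a human glioma cell line grown attached to plastic in medium with serum. Per the labels, the line was plated sparsely, colonies that each grew from 1 cell were picked, and each was expanded as a subclone. The subclones carry the numbers 1, 2, 3, 5, 6, 8, 9, 10, 11 and 12. Per the labels' protocols, cultures were collected during exponential growth after trypsin treatment, total RNA was extracted with a spin-column kit, and biotin-labelled RNA was hybridised to 1-colour Affymetrix arrays. Each subclone was measured on 1 array, so the spread between cultures or arrays of 1 subclone is unknown, and no difference between subclones can be set against it. The p-values below describe these 10 arrays, whose differences may in part be technical. Those for variable genes, list coherence and list enrichment compare genes with other genes on the same arrays. Only those for correlations between scores and for principal components come from permuting or shuffling values over the subclones.

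The deposited table holds 1 log2 value per gene symbol and array for 11880 gene symbols, made by the authors with RMA per the submitters' processing notes. RMA corrects background, quantile-normalizes probe signals and summarises probes on the log2 scale. The unit is not stated in words and was read from the method and the values, which lie between 2.73 and 13.70. The software version, the array annotation and the way in which several probe sets were joined into 1 value per gene are not given in the sources used here. Comparisons between probe sets of 1 gene, and a mean over probe sets, were planned and could not be made from this table. Because RMA aligns the arrays' probe distributions, a difference in total RNA between subclones cannot be seen, and weak signals are compressed toward a common floor. The arrays' values carry no counts or depths, and the number of arrays limits the precision.

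Gene symbols were matched to the RefSeq annotation of GRCh38.p14: 10616 symbols were current, 1082 were matched through an older name, and 182 had no unambiguous match. The annotation was used only for names, chromosome membership, gene order and local gene density; the symbols are printed as the table gives them. VIM was not analysed here. A gene was tested if its highest value over the 10 arrays was at or above the median of all values, 5.00, which left 7095 genes. Genes on the Y chromosome and XIST were not named.

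The comparisons, tests, gene lists, list pairs and alternatives were fixed before the data were examined, except those said here to have been added later. Variable genes were sought with limma's robust variance test: each gene's variance (9 degrees of freedom) was compared with that of genes of like mean expression, through a scaled F distribution fitted with extreme variances winsorized. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The fitted prior had 4.32 degrees of freedom. The non-robust version of the fit (4.03 prior degrees of freedom) and a chi-square test of each variance against the trend were set as alternatives. The tail p-values of this fit were used. Gapped genes were those with at least 1.5 log2 units between neighbouring sorted values, counted against 100 sets of values drawn from normal distributions with each gene's mean and SD.

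A total of 40 gene lists with 919 entries were used, and 97 entries were not matched to the table. Lists with under 5 tested members were not tested, which left 37. Coherence was the mean pairwise Pearson correlation among a list's members over the 10 subclones, compared 1-sided with 10000 random lists of the same size matched on mean expression in 10 bins; the smallest p this can give is 1e-04. A list's relative score in a subclone was the mean of its gene-centred log2 values minus the median of the same random lists, which removes shifts shared by the whole array. Fisher's exact test, 1-sided, compared the share of a list's members past the variance test with that of other tested genes. Correlations between list scores used 100000 permutations, 2-sided. Principal components were computed from gene-centred values and compared with 1000 shufflings of each gene's values over subclones. For chromosomes, the median gene-centred value in each subclone was compared with 10000 random lists matched on mean expression; a median counted as outside their range when fewer than 5 of the 10000 lists lay as far out on that side. This describes single arrays and is not a test of the subclone.

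The rule for named genes took the 15 genes with the largest SD and, for each subclone, the 2 genes farthest from the median of the other 9, all among genes past the variance test; up to 4 members per list past the test, or otherwise the member with the largest SD; and 12 glioma genes named beforehand. As the robust test called 0 genes, the same ranking was applied to genes past the chi-square test, a decision made after that count was seen; up to 4 chi-square members per list were named in the same way.

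The alternatives set beforehand subtracted each array's median over tested genes, repeated a quantile normalization on the table, removed the filter on dim genes or based it on the mean, and left out each subclone in turn. Further ones changed the thresholds, the correlation type, the matching of random lists, the scaling of genes and the list score. For a set of 9 subclones the correlations used exact permutation tests. Added after seeing the data were analyses without subclones 10 and 11, the chi-square count under each setting, the enrichment of lists with chi-square calls, segments of 38 to 52 neighbouring tested genes, and matching on local gene density. Local gene density was the number of protein-coding genes within 1 Mb on either side of a gene's start, which was available for 98.8% of tested genes; random lists were then matched in 5 bins of mean expression by 5 bins of density.

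The variance tests were tested on simulated data of 7095 genes in which 50 genes each were given 2, 3, 4 or 6 times the SD. When the other genes lay on the trend, the robust test recovered 25, 48, 49 and 50 of 50 and called 3 of 6895 unaltered genes. With the variances of all other genes spread as in the data, it recovered 0 of 50 at each size, while the chi-square test recovered 40, 48, 48 and 50 and also called 1305 of the 6895 unaltered genes. The non-robust fit also recovered 0 of 50 at each size with that spread. A robust count of 0 on such data does not show that genes do not differ, and a chi-square call means only that a gene varies more than the trend. For coherence, 20 of 20 simulated lists with a correlation of 0.4 and 1 of 20 without any were called. These lists had 20 genes each, and genes without a shared factor were independent. In the data random lists had a mean r of up to 0.11. Some tested lists were smaller, and some coherent ones had a mean r below 0.4. The simulation does not give the rates of calls for such lists. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.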

Results

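Expression profiles were compared among 10 subclones of the glioma line U87MG, each raised from 1 cell and measured on 1 array. There was no treatment and no second group, so the design asks how subclones of one line differ. Every value given for a subclone comes from a single array without a replicate. The median log2 value per array lay between 4.87 in subclone 10 and 5.11 in subclone 9. Upper quartiles were 6.75 in subclone 10, 7.02 in subclone 11 and 7.17 to 7.36 in the other 8. Over tested genes the median deviation from the gene mean was -0.29 in subclone 10 and 0.11 in subclone 9, and list scores below are relative to random genes of the same arrays. Identical columns were found 0 times. With arrays, their number limits the precision.

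Among genes of known interest in glioma, CD44, a hyaluronan receptor, was expressed at 9.83 ± 0.27 (log2, SD, n = 10), and CHI3L1, a secreted chitinase-like protein, at 11.81 ± 0.73, with 10.17 in subclone 9 and 12.97 in subclone 1. NES, which encodes the intermediate filament nestin, was at 6.74 ± 0.80 and ranged from 5.14 in subclone 5 to 7.55 in subclone 12. EGFR, the epidermal growth factor receptor, was at 4.96 ± 0.30. The tumour suppressor CDKN2A (3.69 ± 0.17), the DNA repair gene MGMT (3.67 ± 0.09), the stem cell marker PROM1 (3.72 ± 0.34), the transcription factor SOX2 (3.74 ± 0.11) and the astrocyte filament GFAP (3.69 ± 0.22) lay below the table's median of 5.00 in all 10 subclones. After each array's median was subtracted, the SDs of CDKN2A, MGMT and SOX2 were 0.35, 0.25 and 0.29.

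Among the genes with the largest spread, IL1B, a proinflammatory cytokine, stood at 12.15 in subclone 9, 8.55 in subclone 11, 8.47 in subclone 6 and 4.43 in subclone 3. COL3A1, a fibrillar collagen, was at 10.05, 9.61 and 9.28 in subclones 2, 3 and 5 and at 3.92 in subclone 1. LBP, a lipopolysaccharide-binding protein, reached 10.49 in subclone 5 and 9.94 in subclone 1 but 4.17 in subclone 8. CFI, a protease that inactivates complement, ranged from 9.95 in subclone 2 to 3.55 in subclone 9, and the matrix proteoglycan LUM from 10.33 in subclone 5 to 3.55 in subclone 11.

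The other genes of the 15 with the largest SD were CXCL2, OLFML3, IL6, CD24, MMP3, JAM2, CSF3, HMGN3, NDN and AMIGO2. MMP3, the matrix protease stromelysin, was at 12.21 in subclone 9 and 9.88 in subclone 1, and below the table's median in subclone 10 (4.39). HMGN3, a nucleosome-binding protein, was at 3.24 in subclone 9 and between 7.77 and 9.47 elsewhere. CD24, a surface glycoprotein, was at 9.26 and 9.20 in subclones 2 and 3 and at 3.68 in subclone 9. The adhesion molecule AMIGO2 spanned 9.18 in subclone 3 to 3.75 in subclone 11.

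Over all 7095 tested genes, 4489 (63.3%) spanned at least a 2-fold range, 915 (12.9%) at least 4-fold and 73 at least 16-fold. The median SD was 0.37. By limma's robust variance test 0 genes varied more than genes of like mean expression, with a lowest adjusted p of 0.600. An unadjusted p under 0.05 was found for 350 genes, against 355 for evenly spread p-values. The test's distribution was fitted to these same variances, so a count near that number was largely built in. It does not show that genes vary only by chance. The non-robust fit also called 0 genes (321 at an unadjusted p under 0.05), and the chi-square test against the trend called 1337 genes (18.8%; 1946 unadjusted). Gene variances in these data were themselves widely spread, and with such a spread the robust test recovered 0 of 50 simulated genes at each of 4 sizes of added variation.

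Each subclone had genes that lay far from the median of the other 9. NTS, the precursor of the peptide neurotensin, was at 8.35 in subclone 12 against a median of 3.65 in the other 9. RCAN2, a regulator of calcineurin, was at 7.67 in subclone 1, against a median of 3.64. MGP, an inhibitor of calcification, was highest in subclone 2 (7.75) and CALCB, a calcitonin gene-related peptide, in subclone 3 (7.82). In subclone 8, the X-linked genes LDOC1 and BEX1 were at 4.30 and 6.57, against medians of 7.74 and 9.18 in the other 9, although LDOC1 was also at 4.46 in subclone 3. TDO2, a tryptophan-degrading enzyme, was at 4.98 in subclone 6 and 4.86 in subclone 11 but between 8.09 and 8.26 in subclones 1, 2, 3, 5 and 9. NDN, an imprinted gene, was at 8.19 in subclone 11 and 7.63 in subclone 9. JAM2, a junctional adhesion molecule, lay at 4.50, 4.66 and 4.16 in subclones 12, 1 and 9 and between 6.79 and 9.31 in the others.

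In total 150 genes had a gap of at least 1.5 log2 units between neighbouring subclones, compared with a mean of 77.7 and a highest count of 97 in 100 sets of normal values. In 127 of them 1 subclone lay apart from the other 9. Subclone 9 lay above all others for 57 genes and below them for 21, subclone 10 above for 22 and below for 3, and subclone 11 above for 4 and below for 6. The 22 in subclone 10 included SSX1, HOXD10, PRB1, DMP1, IBSP and APOC4, on the array with the lowest upper quartile. With 1 array, expression in that subclone cannot be told apart from the state of the array. Without subclone 9 the count of gapped genes was 80, and with a filter on mean expression it was 84. Normal values were not drawn for these settings, so these counts cannot be set against 77.7. The filter on the highest value admits genes bright in only 1 subclone, which favours genes above all others.

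**Figure D1:**
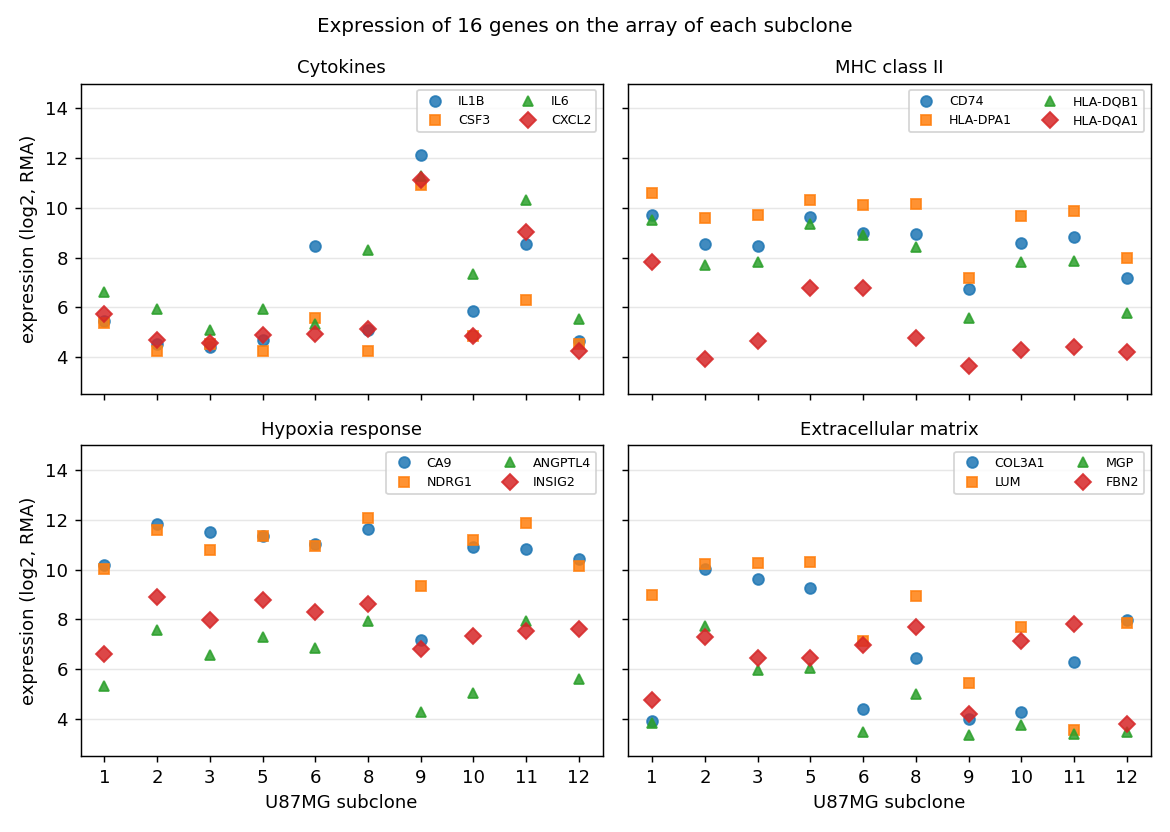
Expression of 16 genes in 4 groups (vertical axis, log2 RMA value) on the array of each subclone (horizontal axis); each point is 1 array. IL1B, CSF3, IL6 and CXCL2 lay between 10.92 and 12.15 in subclone 9, where CA9 was at 7.17 and HLA-DPA1 at 7.16.

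Cytokine and chemokine genes gave the widest range of scores among the lists. The cytokine and NF-kB target list had a relative score of 2.80 in subclone 9, 0.79 in subclone 11 and -0.88 in subclone 3, and 18 of its 20 tested members were highest in subclone 9. IL6 was at 11.29 in subclone 9, 10.32 in subclone 11, 8.32 in subclone 8 and 5.08 in subclone 3. CXCL2, a chemokine for neutrophils, was at 11.14 and 9.04 in subclones 9 and 11 and at most 5.72 in the others. CSF3, a granulocyte growth factor, was at 10.92 in subclone 9 and 6.29 in subclone 11. The members correlated with a mean r of 0.64 (random lists, 0.03; adjusted p = 0.000462). By limma's robust test 9 of 20 members passed adjusted over the list alone and 0 over all genes, with 13 at an unadjusted p under 0.05. The chi-square test called 17 over all genes.

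The protease and invasion list had its highest score in the same subclone, 0.67, but its members were not coherent (mean r = -0.01, adjusted p = 0.904). The collagenase MMP1 was at 8.43 in subclone 9 and at most 4.22 elsewhere, and the elastase MMP12 was at 6.93 there and at most 4.26 elsewhere. The aggrecan-degrading ADAMTS5 ranged from 6.14 in subclone 8 to 9.91 in subclone 9. MMP3 alone of 19 members passed the robust test adjusted over the list alone and 0 passed over all genes (5 at an unadjusted p under 0.05), while the chi-square test called 12.

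Amino acid and integrated stress response genes were highest in subclones 9 (relative score 1.13) and 11 (0.92) and lowest in subclones 5 and 6 (both -0.47). ATF3, a stress-induced transcription factor, was at 9.14 in subclone 9, 7.75 in subclone 11 and at most 5.54 elsewhere. TRIB3, a pseudokinase of the same response, was at 8.18 in subclone 11 and 6.23 in subclone 9. PSAT1, an enzyme of serine synthesis, and CTH, of cysteine synthesis, were highest in subclone 9, at 7.64 and 6.96. The list was coherent (mean r = 0.58, adjusted p = 0.000462); by the robust test 0 of 19 members passed adjusted over the list alone or over all genes (7 at an unadjusted p under 0.05) and 12 by chi-square over all genes.

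Hypoxia response genes varied together and were lowest in subclone 9. Their relative score was -1.02 in subclone 9 and -0.67 in subclone 1, against 0.63, 0.62 and 0.57 in subclones 2, 8 and 5. CA9, the hypoxia-induced carbonic anhydrase, was at 7.17 in subclone 9 and between 10.21 and 11.83 elsewhere. NDRG1 ranged from 9.34 in subclone 9 to 12.07 in subclone 8, and the lipase inhibitor ANGPTL4 from 4.29 to 7.95 in the same subclones. Coherence was high (mean r = 0.72, adjusted p = 0.000462); by the robust test CA9 and NDRG1 passed adjusted over the list alone and 0 over all genes (11 of 18 at an unadjusted p under 0.05), and by chi-square all 18 did.

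Glycolysis genes showed a smaller range, from -0.48 in subclone 9 to 0.22 in subclone 8, and were coherent (mean r = 0.31, adjusted p = 0.000462). The aldolase gene ALDOC ranged from 8.07 in subclone 10 to 10.67 in subclone 2, and the glucose transporter SLC2A1 from 4.71 in subclone 9 to 7.01 in subclone 2. Of 20 members 0 passed the robust test adjusted over the list alone or over all genes (1 at an unadjusted p under 0.05), and 5 passed by chi-square. The metal-binding metallothioneins scored 0.76 in subclone 6 and -0.84 in subclone 9 (mean r = 0.43, adjusted p = 0.00655). MT3 was at 9.38 in subclone 8, 9.23 in subclone 2 and 4.32 in subclone 9, and it alone of 7 members passed the robust test adjusted over the list alone, with 0 over all genes (3 at an unadjusted p under 0.05) and 4 by chi-square. The list's coherence did not pass without subclone 6 (mean r = 0.27).

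MHC class II genes, which present antigens to helper T cells, had the highest coherence of all lists (mean r = 0.84, adjusted p = 0.000462). Their relative score was 1.52 in subclone 1, 1.05 in subclone 5 and 0.84 in subclone 6, and it was -1.93 in subclone 9 and -1.24 in subclone 12. CD74, the invariant chain of these molecules, was at 9.71 in subclone 1, 7.17 in subclone 12 and 6.74 in subclone 9. HLA-DPA1 was at 10.58, 7.97 and 7.16 in the same subclones and HLA-DQB1 at 9.52, 5.77 and 5.56. HLA-DQA1 was above the table's median in subclones 1, 5 and 6 (7.83, 6.76 and 6.77) and at most 4.77 elsewhere. Of 6 members 5 passed the robust test adjusted over the list alone and 0 over all genes (5 at an unadjusted p under 0.05), and 6 passed by chi-square.

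MHC class I and antigen processing genes spanned a narrower range, 0.22 in subclone 1 to -0.27 in subclone 12. HLA-B was between 11.10 and 11.97, and the peptide transporter TAP1 between 6.08 in subclone 2 and 7.97 in subclone 1. Their coherence was near the threshold (mean r = 0.22, adjusted p = 0.0455) and did not pass in 9 of 17 alternatives. Among these were the fits without subclone 1 (mean r = 0.19), 5 (0.21), 6 (0.21), 11 (0.21) or 12 (0.21). Interferon response genes were not coherent (mean r = 0.10, adjusted p = 0.335), with scores from 0.37 in subclone 1 to -0.33 in subclone 11. MX2, an antiviral GTPase, was at 6.62 in subclone 5 and 3.71 in subclone 10. By the robust test 0 members of either list passed adjusted over the list alone or over all genes. At an unadjusted p under 0.05 these were 0 of 12 MHC class I and 1 of 14 interferon response genes, and by chi-square 4 and 5.

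Collagen and fibrillar matrix genes were highest in subclones 2 (relative score 0.76) and 5 (0.52) and lowest in subclone 9 (-1.05). Besides COL3A1, LUM and MGP, the fibrillin FBN2 ranged from 7.83 in subclone 11 to 3.79 in subclone 12. By the robust test 9 of 20 members passed adjusted over the list alone and 0 over all genes (9 at an unadjusted p under 0.05), and 15 passed by chi-square. Coherence was weak (mean r = 0.16, adjusted p = 0.0206) and did not pass in 4 of 17 alternatives, among them the analysis without subclone 2 (mean r = 0.13).

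Other adhesion and signalling lists were not coherent. Basement membrane and integrin genes (mean r = 0.04, adjusted p = 0.406) scored lowest in subclone 9 (-0.37), with the nidogen NID2 at 7.03 there and 9.69 in subclone 8. TGF-beta and contractile genes (mean r = 0.21, adjusted p = 0.0906) were also lowest in subclone 9 (-0.47), and the myosin light chain MYL9 ranged from 6.86 in subclone 11 to 9.02 in subclone 12. YAP and TEAD targets (mean r = 0.17, adjusted p = 0.188) scored -0.32 in subclone 10 and -0.30 in subclone 11; their member AMOTL2 was at 4.78 and 4.32 there and at 8.02 in subclone 2. Receptor tyrosine kinases and ligands (mean r = 0.06, adjusted p = 0.373) included IGFBP3, an insulin-like growth factor binding protein, at 8.56 in subclone 9 and 13.05 in subclone 8, the only one of 18 members past the robust test adjusted over the list alone, with 0 over all genes. Cadherins and protocadherins had a mean r of 0.04 (adjusted p = 0.406), with PCDH17 between 4.04 and 6.12. In the other 4 lists the robust test called 0 members over either set. At an unadjusted p under 0.05 it called 1 basement membrane, 1 TGF-beta, 4 YAP, 3 receptor kinase and 0 cadherin genes, and the chi-square test called 7, 6, 7, 10 and 1.

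Genes of mitosis and DNA replication were coherent. Mitotic genes of the G2/M list scored 0.34 in subclone 6 and -0.65 in subclone 5, where 13 of 22 members were lowest. The kinetochore motor CENPE ranged from 4.09 in subclone 11 to 7.30 in subclone 3, and the spindle motor KIF11 from 4.70 to 7.25. This list was coherent (mean r = 0.58, adjusted p = 0.000462), and so was DNA replication (mean r = 0.25, adjusted p = 0.00740), which scored 0.25 in subclone 6 and -0.23 in subclone 5. The histone mRNA-binding protein SLBP ranged from 8.03 in subclone 10 to 9.72 in subclone 2. Without subclone 6 the DNA replication list was not past the threshold (mean r = 0.18). Histone genes were not coherent (mean r = 0.03, adjusted p = 0.406); HIST2H2BE ranged from 4.60 in subclone 11 to 7.14 in subclone 12. By the robust test 0 members of these 3 lists passed adjusted over the list alone or over all genes. At an unadjusted p under 0.05 it called 1 G2/M, 0 DNA replication and 1 histone gene, and the chi-square test called 8, 3 and 4.

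Of 7 metabolic, housekeeping and heat shock lists, 6 were coherent. Oxidative phosphorylation genes (mean r = 0.38, adjusted p = 0.000462) scored 0.31 in subclone 9 and -0.22 in subclone 2, and the cytochrome CYC1 ranged from 8.72 in subclone 3 to 10.47 in subclone 9. Ribosomal protein genes (mean r = 0.37, adjusted p = 0.000462) stayed between -0.13 and 0.19, with RPL27 at 9.61 to 10.86. Random lists for coherence were matched on mean expression only. A part of these lists' coherence that follows the arrays' trend with local gene density was therefore not separated. Cholesterol synthesis genes (mean r = 0.33, adjusted p = 0.00789) scored 0.38 in subclone 11 and -0.40 in subclone 3. INSIG1, a regulator of sterol synthesis, lay between 8.14 in subclone 1 and 9.92 in subclone 8. Fatty acid synthesis and desaturation was not coherent (mean r = 0.16, adjusted p = 0.406), and the desaturase SCD ranged from 5.62 in subclone 1 to 8.39 in subclone 8. Endoplasmic reticulum chaperones (mean r = 0.30, adjusted p = 0.00185) scored 0.31 in subclone 11 and 0.30 in subclone 9, with the co-chaperone DNAJB9 at 7.23 in subclone 9 and 4.66 in subclone 6. Heat shock genes (mean r = 0.34, adjusted p = 0.000822) scored 0.36 in subclone 12 and -0.33 in subclone 11, and the small heat shock protein CRYAB ranged from 8.43 in subclone 1 to 4.01 in subclone 9. Lysosome and autophagy genes (mean r = 0.23, adjusted p = 0.00401) stayed between -0.20 and 0.20; the protease CTSF ranged from 5.10 to 7.61. By the robust test 0 members of these 7 lists passed adjusted over the list alone or over all genes, and at an unadjusted p under 0.05 only 1 heat shock gene did. The chi-square test called 5 oxidative phosphorylation, 1 ribosomal, 1 cholesterol, 2 fatty acid, 7 chaperone, 5 heat shock and 4 lysosome genes. After each array's median was subtracted, the chaperone (mean r = 0.29), heat shock (0.31) and lysosome (0.06) lists were not coherent.

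Heat shock and immediate early genes were both included as handling-related. Heat shock genes were coherent (mean r = 0.34, adjusted p = 0.000822), though not after each array's median was subtracted. Immediate early genes were not coherent (mean r = 0.07, adjusted p = 0.539), although FOS ranged from 3.31 in subclone 10 to 6.86 in subclone 12. Targets of the oxidative stress factor NRF2 were not coherent either (mean r = 0.06, adjusted p = 0.406), and AKR1C3, an aldo-keto reductase, was at 5.38 in subclone 9 and between 8.49 and 9.50 elsewhere. By the robust test 0 immediate early and 0 NRF2 genes passed adjusted over the list alone or over all genes. In each of these lists 2 had an unadjusted p under 0.05 and 6 passed by chi-square.

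None of the tested lists of lineage markers was coherent. Astrocyte markers (mean r = 0.14, adjusted p = 0.135) scored 0.61 in subclone 5 and -0.46 in subclone 11. The glutamate transporter SLC1A3 was at 9.35 in subclone 1 and 5.42 in subclone 10, and ID3, a transcription inhibitor, ranged from 7.37 to 10.35; by the robust test SLC1A3, ID3 and ALDOC passed adjusted over the list alone and 0 over all genes, with 5 of 9 at an unadjusted p under 0.05 and 8 by chi-square. Neural stem and progenitor markers (mean r = 0.16, adjusted p = 0.406) scored 0.59 in subclone 3, and CD24 alone of 7 members passed adjusted over the list alone, with 0 over all genes, 1 at an unadjusted p under 0.05 and 5 by chi-square. Neuronal markers (mean r = -0.03, adjusted p = 0.633) included SYT1 at 6.26 in subclone 9 and at most 3.76 elsewhere. Mesenchymal glioma markers (mean r = -0.01, adjusted p = 0.832) stayed between -0.24 and 0.11, and glioma driver and drug response genes (mean r = 0.07, adjusted p = 0.498) between -0.17 and 0.18, with the interleukin receptor IL13RA2 from 8.73 in subclone 12 to 11.63 in subclone 9. Only 4 proneural, 3 epithelial and 2 leukocyte markers were bright enough to be tested. PDGFRA, a growth factor receptor, ranged from 3.96 in subclone 9 to 8.38 in subclone 3, and MUC1 from 4.29 to 6.67. CD2 was at 6.28 in subclone 10 and at most 4.82 elsewhere, and an effect of the subclone 10 array cannot be told apart. Endothelial and pericyte markers (mean r = -0.07, adjusted p = 0.677) included the vessel growth factor ANGPT1, from 3.87 in subclone 11 to 7.36 in subclone 5. In the neuronal, mesenchymal, glioma driver and endothelial lists the robust test called 0 members over either set, 1, 2, 2 and 1 at an unadjusted p under 0.05, and the chi-square test called 5, 5, 7 and 2.

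Among germline and imprinted genes, some were high in 1 subclone and others in several. The X-linked cancer-testis gene MAGEA1 was at 8.52 in subclone 9 and at most 3.60 elsewhere, MAGEC1 was at 7.94 and at most 3.64, and SSX1 was at 7.25 in subclone 10 and at most 5.63. On the subclone 10 array 22 genes, not only of these lists, lay at least 1.5 log2 units above all others. An array effect on SSX1, or on HOXD10 below, cannot be told apart. MAGEC2 was at 7.86, 7.65, 7.38 and 7.36 in subclones 10, 5, 12 and 9 and at most 4.86 in the other 6. In the cancer-testis list 4 of 5 tested members passed the robust test adjusted over the list alone, 0 over all genes, 4 at an unadjusted p under 0.05 and 4 by chi-square, without coherence (mean r = 0.09, adjusted p = 0.373). Of 11 imprinted genes, MEST, NDN and DIRAS3 passed the robust test adjusted over the list alone, 0 over all genes, 3 at an unadjusted p under 0.05 and 4 by chi-square (mean r = -0.06, adjusted p = 0.961). DIRAS3, a growth-suppressing GTPase, was at 10.52 in subclone 12 and 4.72 in subclone 9. HOX genes (mean r = 0.01, adjusted p = 0.473) included HOXC6 at 5.37 in subclone 11 and between 6.91 and 8.10 elsewhere, and HOXD10 at 6.31 in subclone 10 and at most 4.64 elsewhere. Of 11 HOX genes, 0 passed the robust test adjusted over the list alone or over all genes, 0 at an unadjusted p under 0.05, and 5 by chi-square.

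Over the 37 lists, 17 were coherent and 18 had an unadjusted p under 0.05. Fisher's exact test on robust calls found 0 lists enriched, and 0 at an unadjusted p under 0.05. As the robust test called 0 genes, no list could have been found enriched, and this count says nothing about the lists. With chi-square calls Fisher's test found 11, and 20 unadjusted. The plot of list scores shows 16 of the coherent lists. In 14 of the 37 lists the highest or lowest score was that of subclone 9. Subclone 11 also held it in many lists, among them ribosomal proteins, cholesterol synthesis, astrocyte markers and heat shock genes.

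**Figure D2:**
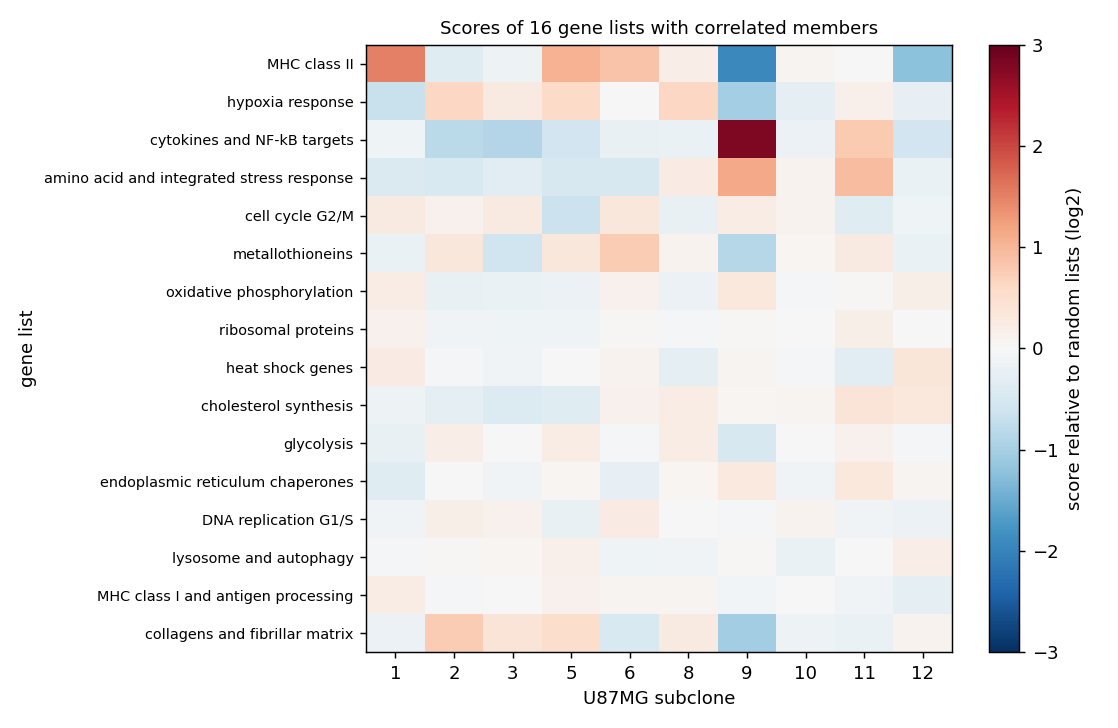
Relative scores (colour, log2) of 16 coherent gene lists (down the side) in the 10 subclones (across), 1 array each. The cytokine list reached 2.80 and the MHC class II list -1.93 in subclone 9.

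Scores of hypoxia response and glycolysis genes were correlated over the 10 subclones, with Pearson r = 0.98 (permutation p = 1e-05, the smallest attainable; adjusted p = 7e-05) and Spearman rho = 0.95 (permutation p = 6e-05). Without subclones 1 and 9, the farthest from the median, r was 0.96. Among the 7 pairs of lists tested, 3 others passed. Cholesterol and fatty acid synthesis had r = 0.81 (permutation p = 0.00715, adjusted p = 0.025), rho = 0.79 (permutation p = 0.00925) and r = 0.90 without subclones 3 and 12. The G2/M and DNA replication lists had r = 0.77 (permutation p = 0.0135, adjusted p = 0.0316), rho = 0.89 (permutation p = 0.00103) and r = 0.69 without subclones 5 and 11. Cytokine and protease scores had r = 0.85 (permutation p = 0.0283, adjusted p = 0.0496) but rho = 0.53 (permutation p = 0.123), and r = 0.10 without subclones 9 and 11, so this relation rests on those subclones; without subclone 9 alone r was 0.18. Of 16 alternative settings, the call at an adjusted p below 0.05 was lost in 11 for cytokines and proteases, in 7 for G2/M and DNA replication, in 2 for cholesterol and fatty acid synthesis and in 0 for hypoxia and glycolysis. For G2/M and DNA replication it was lost without subclone 3, 5, 6, 10 or 11 (r = 0.74, 0.75, 0.73, 0.76 and 0.72), without 10 and 11 together (0.68, a setting chosen after seeing the data) and after each array's median was subtracted (0.66).

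The remaining 3 pairs did not pass by Pearson's r. Interferon and MHC class I scores had r = 0.64 (permutation p = 0.0491, adjusted p = 0.0687), rho = 0.75 (permutation p = 0.0172) and r = 0.39 without subclones 1 and 11. By Spearman's rho this pair passed (adjusted permutation p = 0.0301), and by Pearson's r it passed without subclone 8 (r = 0.73) or 12 (r = 0.82). Cytokine and protease scores did not pass by Spearman's rho (adjusted permutation p = 0.172). TGF-beta and YAP target scores had r = 0.36 (permutation p = 0.31, adjusted p = 0.362), rho = 0.01 (permutation p = 1) and r = 0.49 without subclones 9 and 11. For G2/M and collagen scores r was -0.20 (permutation p = 0.586, adjusted p = 0.586), rho was -0.22 (permutation p = 0.535) and r was -0.13 without subclones 5 and 11. Leaving out subclone 9 turned the sign of the last value (r = 0.02). The number of pairs past the threshold was 1 without subclone 10 and also 1 without subclones 10 and 11; it was 2 when subclone 3, 5, 6 or 11 was left out.

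Subclones 2, 3 and 5 resembled one another most. Subclones 2 and 5 had a correlation across gene-centred values of 0.68 and differed at least 2-fold in 85 genes (1.20%). Subclones 2 and 10 differed that much in 1642 genes (23.1%). Shifts of whole arrays were not removed from these counts. The median deviation of tested genes was -0.29 in subclone 10 and 0.06 in subclone 2, which adds to the count for that pair. Genes are not independent replicates. The first principal component took 34.3% of the variance, the second 24.2% and the third 13.0%, all above the highest shuffled shares of 12.9%, 12.4% and 11.9% (permutation p = 0.001 each, the smallest attainable). The first placed subclones 5, 2 and 3 (0.33, 0.33 and 0.31) opposite subclones 10 and 11 (-0.47 and -0.37), and the second set subclone 9 apart (-0.63). Scores on the first component were correlated with the arrays' upper quartiles, a single relation examined: r = 0.83 (permutation p = 0.00123), rho = 0.72 (permutation p = 0.0242), and r = 0.52 without subclones 10 and 11.

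Median levels of genes on single chromosomes, or on part of one, differed between subclones. Chromosome 4 genes (227 tested) had relative medians of 0.35 in subclone 2, 0.33 in subclone 8, 0.26 in subclone 3 and 0.19 in subclone 5, against -0.32 in subclone 12, -0.23 in subclone 10 and -0.18 in subclone 9. Only in subclone 12 did all 5 segments of neighbouring genes on chromosome 4 lie outside the range of random lists, against 4 in subclones 2 and 8, 3 in subclones 3, 5 and 10 and 1 in subclone 9. In subclone 5 the segments were at 0.56, 0.44, -0.15, -0.03 and 0.25 in order along the chromosome. Chromosome 3 genes were at -0.29 in subclone 1, chromosome 8 genes at -0.26 in subclone 3, chromosome 14 genes at 0.21 in subclone 6 and chromosome 22 genes at 0.24 in subclone 12. Chromosome 18 genes were at 0.33 in subclone 9 and X-linked genes at 0.25 in subclone 10, but in both only part of the chromosome lay outside the range of random lists. As values are centred on the mean of the 10 subclones, a shift in one subclone moves the others the opposite way. Of 230 chromosome medians 84 lay outside the range of random lists, where 0.23 were expected for independent genes. With lists also matched on local gene density the number was 75, and chromosome 4 lay outside in 9 subclones under either matching.

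Of 1630 medians of segments of neighbouring genes, 170 lay outside that range, and 154 with matching on density. The largest was 0.81 for the 52 tested genes from ZNF271 to ADNP2 on chromosome 18 in subclone 9 (0.70 with matching on density), while the other 52 genes of that chromosome, from USP14 to DTNA, were at -0.00257 and inside the range. The 43 genes from SH3YL1 to KIF3C on chromosome 2 were at -0.65 in subclone 1. These segments were picked after their values were seen. On the X chromosome in subclone 10, the 3 segments from ZNF711 to VAMP7 were at 0.36, 0.45 and 0.43. The 3 segments before them, from GTPBP6 to SATL1, were at -0.02, 0.09 and 0.14 and inside the range.

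**Figure D3:**
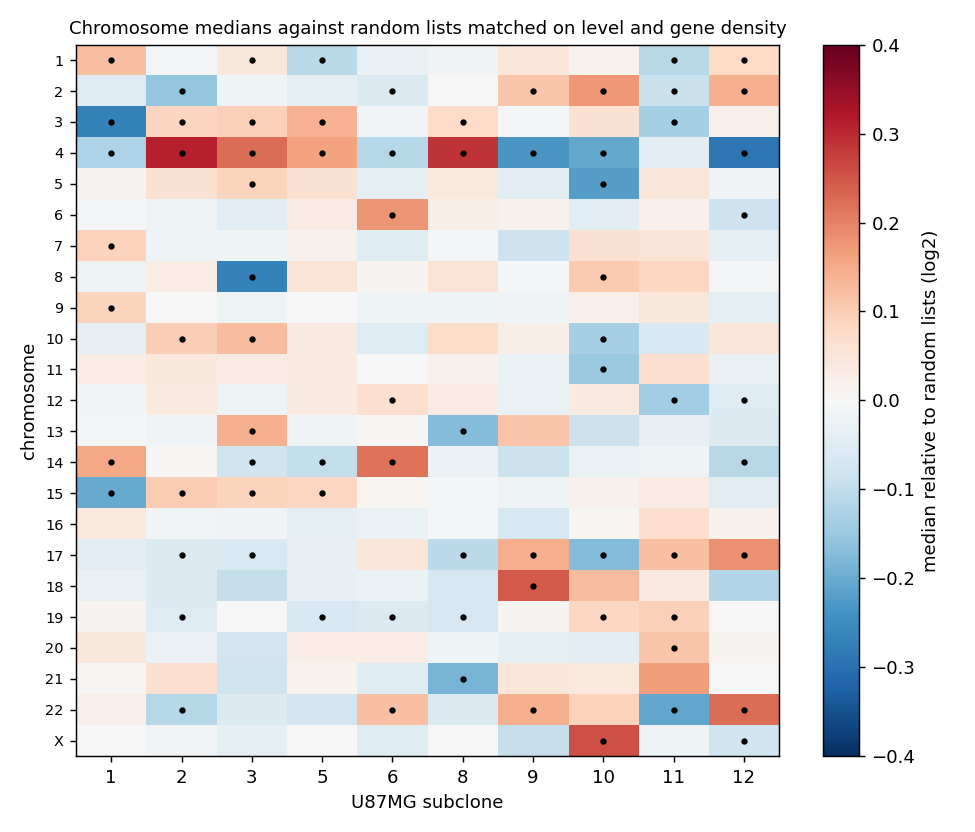
Median deviation of the tested genes of each chromosome (down the side) in each subclone (across), relative to random lists matched on mean expression and local gene density (colour, log2). Black points mark the 75 values outside the range of random lists; chromosome 4 has 9 of them.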

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

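The tests on local gene density and without subclones 10 and 11 were added after the data were examined, and the bounds of each test were written before its result was seen. Values that stand far from the other 9 subclones, by Dixon's ratio of the gap to the whole range, were sought among 97 sets of 10 values. Of these, 16 had such a value, 7 of them in subclone 9 and 4 in subclone 10. Chance gives about 1 in 20 sets of independent normal values. That rate is only a rough guide for the 3 of 37 lists, 6 of 23 chromosomes and 1 of 3 array measures. In the cancer-testis and protease lists, members such as MAGEA1 and MMP1 reached the threshold for testing only in subclone 9. The rate does not hold for those scores. Nor does it apply to the 6 of 34 genes, since all of these except PROM1 were named for a large SD or for lying far from the other 9 subclones. Over all tested genes 885 (12.5%) had such a value, of which 361 were in subclone 10, 315 in subclone 9 and 111 in subclone 11.

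In subclone 9, the cytokine IL1B at 12.15, the growth factor CSF3 at 10.92 and the nucleosome-binding protein HMGN3 at 3.24 stood apart from medians of 5.10, 4.55 and 9.11 in the other 9. So did the relative scores of the cytokine list at 2.80, the cancer-testis list at 1.95 and the protease list at 0.67, and the median of chromosome 18 genes at 0.33, which came from 1 of its 2 segments (0.81, against -0.00257 for the other). In subclone 10, the median deviation of tested genes of -0.29, the stem cell marker PROM1 at 4.61, chromosome 5 genes at -0.23 and X-linked genes at 0.25 stood apart from the other 9. Of their segments, 2 of 8 on chromosome 5 and 3 of 6 on the X chromosome lay outside the range of random lists. In subclone 1, RCAN2 at 7.67 and chromosome 15 genes at -0.22 did. The peptide gene NTS at 8.35 stood apart in subclone 12, chromosome 6 genes at 0.17 in subclone 6 and chromosome 8 genes at -0.26 in subclone 3. Of the segments, 3 of 5 on chromosome 15, 5 of 8 on chromosome 6 and 5 of 6 on chromosome 8 lay outside that range in these subclones.

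The first pattern is the high level of cytokine and stress response genes in subclone 9. Another cell line that keeps the 9p21 genes is argued against by MTAP, CDKN2A and CDKN2B, of which the highest in subclone 9 was at 3.57, below the table's median of 5.00. Leukocytes in the culture are argued against by PTPRC, TYROBP, CD14 and LYZ, of which the highest was at 3.89 there. A scaling difference of the array is argued against by the cytokine score, which was 2.82 as a plain mean of centred values after a second quantile normalization. A different state of that 1 culture at harvest could not be examined with 1 array per subclone, and no biological explanation was tested.

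The second pattern is the first principal component, which set subclones 2, 3 and 5 against subclones 10 and 11. An array-wide difference in the distribution of values is argued against as its whole cause, since the scores correlated with the earlier ones at 0.958 after a second quantile normalization. A trend with local gene density is argued against likewise, with a correlation of 0.935 after each array's median was removed within bins of density. Lower signal on the arrays of subclones 10 and 11 stays open, because without them the correlation over the other 8 subclones was 0.735, between the bounds set for either reading. No biological explanation was tested.

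The third pattern is the shift of chromosome 4 genes, whose medians lay outside the range of random lists in 9 subclones. For a single cluster of neighbouring genes, only the signs of its 4 parts of equal gene number were compared. All had the sign of the whole in 7 of the 9 subclones, though not in subclones 5 and 6. This argues against a single cluster in those 7 except subclone 9. In subclone 9 the parts were at -0.31, -0.22, -0.10 and -0.05. Only the segment from PIGG to RFC1 lay outside the range there, so like signs cannot decide. A trend with local gene density is argued against by the 9 subclones outside with random lists matched on density too. The bias of probes with base composition was not examined, and no biological explanation was tested.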

How the results depend on the processing

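The analyses without subclones 10 and 11, those with local gene density, the chi-square counts under each setting and list enrichment with chi-square calls were chosen after seeing the data. The robust count of variable genes was 0 in all settings of that test, and the chi-square test called 1337 genes; that count was 2421 with no filter on dim genes, where more genes were tested, and 925 to 1410 in its other settings. The 150 gapped genes became 84 with a filter on mean expression, which tests fewer genes, 490 with a gap of 1 and 61 with a gap of 2; leaving out each subclone gave 80 (without subclone 9) to 187. Lists enriched in variable genes numbered 11 by chi-square calls. By robust calls they numbered 0, the only outcome possible with 0 genes called. Coherent lists numbered 13 to 18, the share of the first component was 30.9% to 44.4%, and chromosome medians outside the range numbered 72 to 89. The 4 list pairs past the threshold became 1 without subclones 10 and 11; leaving out each subclone gave 1 (without 10) to 5, with 2 without subclone 3, 5, 6 or 11, and the cause was not tested. Reversed were the coherence of lysosome genes relative to random lists (0.0567 after each array's median was subtracted) and the correlation of TGF-beta and YAP scores (-0.28 after that step, -0.0927 after a second quantile normalization, -0.31 without subclones 10 and 11). Leaving out each subclone gave -0.40 (without subclone 2) to 0.0240 (without subclone 9) for the correlation of G2/M and collagen scores, and the cause was not tested. Agreement between probe sets and every alternative with the mean of all probe sets were not run, because the table holds 1 value per gene. Genes too dim to be tested had a smaller spread (median SD 0.18, against 0.37 for tested genes). The filter itself favours this, since a gene with any value at or above 5.00 was tested. Differences in dim genes may still be less visible, as weak signals are compressed toward a common floor.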

Other observations

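Genes of low and high local gene density deviated differently on the arrays, a relation examined only after the data were seen. From the tenth of genes with the fewest neighbours to the tenth with the most, the median deviation was 0.15 and -0.02 in subclone 2, 0.07 and -0.10 in subclone 8, -0.10 and 0.08 in subclone 1, and -0.15 and 0.05 in subclone 11. Chromosome 4 genes had a median of 13 protein-coding genes within 1 Mb and chromosome 19 genes 59, against 22 for all tested genes. The coherence of gene lists was not tested against random lists matched on density.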
